A study of Arabidopsis thaliana with 12 samples.

How the data were processed

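RNA from whole roots of Arabidopsis thaliana, ecotype Columbia, was measured on 12 one-colour Affymetrix arrays. Per the labels' protocols, seedlings grew for 5 days on standard medium and were then moved either to fresh standard medium, which is the 0 h group, or to sulfur-deficient medium for 3, 12, 24, 48 or 72 h. Each of the 6 groups had 2 arrays. Total RNA was taken with a column kit and turned into biotin-labelled cRNA by the manufacturer's one-cycle protocol, per the labels. The labels number the replicates without saying that they came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

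The deposited values are linear intensity signals, 1 per probe set and array, and the submitters' processing notes name MAS5, the Affymetrix summarisation method, with no version. MAS5 subtracts a local background and combines the probe pairs of a probe set into 1 signal. The scaling target is not given in the sources used here. The 2% trimmed means of the 12 arrays lay between 250.02 and 250.03, so the arrays had the same scale and the intensity values were used as deposited, with log2 of the value and no offset. The table held 22810 probe sets, of which 64 were controls. It had no detection calls, so the background level of a probe set was not known, and log2 differences that involve a dim signal are uncertain in size. Median signals of the arrays ran from 80.7 to 87.9.

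A probe set was tested if it was no control and its value lay above the 40th percentile of the array, which was a signal of 45.3 to 50.4, on at least 2 arrays. This left 14678 of 22746 probe sets. Differences were fitted with limma 3.58.1 in R 4.3.3 as group means over all 12 arrays, with 6 residual degrees of freedom, a prior variance that follows the signal (eBayes with trend) and Benjamini-Hochberg adjustment over the probe sets tested. The threshold was an adjusted p of 0.05. Each later time was compared with 0 h and with the time before it, and a moderated F test over the 5 differences from 0 h asked whether a probe set differed at any time. The small number of arrays limits the precision. On simulated arrays with the measured spread, in which 200 of 14678 probe sets were changed at 3 h, the fit recovered 9 of 62 changes of 1.5-fold, 49 of 69 of 2-fold and 64 of 69 of 4-fold, with 6 false calls. In the data 1755 passed at 3 h, a larger share. The adjustment is less strict where more probe sets change, so these rates need not hold for the data.

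Gene names came from the platform table given with the data, which paired 13513 probe sets with 1 gene symbol and 503 with several and left 8730 unlisted. Probe sets with several genes were not named. Symbols were updated by gene number through the gene table of assembly TAIR10.1, in which 13436 probe sets matched. Where a gene had several probe sets, the one with the highest mean log2 value stood for it. No coordinates are given, because the build behind the array's files is not given in the sources used here.

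The following were chosen before the data were examined. The genes named are, at each time against 0 h, the 10 with the highest and the 10 with the lowest log2 difference among those past the threshold whose 2 arrays both lay on the same side of both 0 h arrays, up to 4 members of each gene list by p, and every measured member of the sulfate transporter, sulfate assimilation and sulfur deficiency marker lists. Between successive times the 5 highest and 5 lowest were taken, and for the whole course the 10 with the smallest p of the F test. There were 23 gene lists with 399 entries, of which only 54 had a probe set paired with that gene alone. Lists with at least 3 tested members were tested against all other probe sets with camera, with a preset correlation of 0.01 between genes, and adjusted over the lists within a time. Camera with an estimated correlation and fry were run beside it. Fry asks whether the members of a list differ between groups, without setting them against the other probe sets. Its p-values are given for the differences from 0 h and are not adjusted over lists. Of the 23 lists, 7 could be tested. Below, a measured member is one with a named probe set that passed the filter. Other members may be on the array under unlisted probe sets. No probe set could be named for the lists of sulfate transporters, jasmonate, phosphate starvation, suberin synthesis, and xylem and phloem, and no named probe set passed the filter for abscisic acid response and for flavonoid and anthocyanin synthesis.

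The alternatives were an offset of 16.3 added before log2, which is the median over arrays of the 25th percentile, quantile normalization, no filter, a stricter filter, no trend of the prior variance, the replicate number as a block, a fit of the compared groups alone, and leaving out each of the 12 arrays. The difference from 3 h to 72 h, a list of carbon starvation genes, gene families by symbol stem and a comparison of times set against different 0 h arrays were added after the data had been examined.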

Results

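The series followed gene expression in whole Arabidopsis roots over 72 h after seedlings were moved to sulfur-deficient medium, with roots moved to fresh standard medium as the 0 h control. There were 12 arrays, 2 at each of 0, 3, 12, 24, 48 and 72 h. Log2 signals of the 2 arrays of a group correlated across probe sets at 0.966 to 0.982, while correlations over all pairs of arrays ran from 0.917 to 0.985. No later time had a control on standard medium, so the effect of sulfur deficiency could not be separated from that of transfer, seedling age or hour of harvest, and "changed" below means different from 0 h. The ratio of 3' to 5' signal of the actin control was 2.38 to 3.44, and that of the GAPDH control 0.834 to 1.24, over the 12 arrays. The highest actin ratio and the lowest GAPDH ratio both belonged to 3 h arrays, as did the highest such ratio of the ubiquitin control.

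After 3 h, the comparison with 0 h asked for the earliest response. BGLU28, a beta-glucosidase known to rise when sulfur is short, had the highest log2 difference among named genes, 7.29 ± 0.31 (SE, adjusted p = 9.65e-09). Its signal was 14.9 ± 1.27 (SD, n = 2) at 0 h and 2377 ± 633 (SD, n = 2) at 3 h, and both 0 h values were below the 40th percentile of their arrays. AT1G04770, also known as SDI2 and a marker of sulfur deficiency, rose by 2.58 ± 0.18 (SE, adjusted p = 5.75e-07). Both measured members of the sulfur deficiency marker list rose. In sulfate assimilation, 1 of 3 measured members rose over all probe sets and 2 when adjusted over the list alone. ATP sulfurylase APS3 rose by 1.82 ± 0.18 on the log2 scale, while APS4 stood at -0.24 and sulfite reductase SIR at 0.36, neither past the threshold over all probe sets. The list as a whole did not pass (adjusted p = 0.0843), and passed with no filter (adjusted p = 0.0435).

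Genes of glucosinolate synthesis, which makes the sulfur-rich defence compounds of this plant family, were higher at 3 h. Of 4 measured members 3 rose, and 4 rose when adjusted over the list alone. BCAT4, the aminotransferase that starts the chain elongation of methionine, rose by 1.15, the glucosyltransferases AT2G31790 (UGT74C1) by 1.03 and UGT74B1 by 0.91, and the glutathione transferase GSTU20 stood at 0.64. The call of AT2G31790 was lost without any 1 of the 4 arrays compared. The list shifted upward (adjusted p = 0.00118 with camera), a call lost with an estimated correlation (adjusted p = 0.184). Glutathione transferase GSTU25 rose by 1.52, and GSTU26 stood at -0.15. The other highest log2 differences at 3 h were 3.89 for AT1G49000, 3.49 for AT1G12030 and AT4G37290, 3.01 for the aldo-keto reductase family gene AT1G60750, 2.65 for the glycosyltransferase family gene AT2G22590, 2.62 for AT1G72490, 2.60 for AT4G36010 and 2.57 for the isoflavone reductase-like gene AT1G75290. AT1G12030 was below the 40th percentile on both arrays at 0 h and at 3 h, and with an offset its difference of 0.87 no longer passed. The size of a difference is uncertain where a group lay below that percentile, as AT1G49000, AT1G72490 and AT1G75290 did at 0 h. With the offset AT1G49000 stood at 1.77 and AT1G75290 at 1.46, both past the threshold.

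Falls at 3 h were as large. GAT1_2.1, a glutamine amidotransferase, fell by 8.79 ± 0.92 on the log2 scale, from a signal of 3025 ± 542 (SD, n = 2) to 16.9 ± 21.9 (SD, n = 2). With an offset its difference was -6.68. AT3G15450 fell by 4.73 ± 0.35 from a mean signal of 6857 to 283.5, and the glycerate kinase AT1G80380 fell by 4.06 ± 0.24 from 1595 to 95.6. AT5G61590 (DEWAX, an ethylene response factor that represses wax synthesis) had a log2 difference of -3.61 and AT2G20670 of -3.46. The cytochrome P450 gene CYP718, AT3G23880, AT1G33055, AT5G56100 and CCL also fell. They and GAT1_2.1 were below the 40th percentile on both 3 h arrays, so the size and order of their falls are uncertain. With an offset the differences were -3.37 for CYP718, -3.21 for AT1G33055, -3.02 for AT5G56100, -2.71 for AT3G23880 and -2.16 for CCL, all past the threshold. The root hair expansins EXPA7 and EXPA18 were lower, with differences of -1.77 and -1.08, and the clock gene GI rose by 1.61 ± 0.19. In the auxin response list, GH3.3 fell by 0.99 and WES1 (GH3.5) fell by 1.25, both of which join auxin to amino acids, while LBD16 stood at 0.00. Without 3 h replicate 2 GH3.3 stood at -0.58 and did not pass, and EXPA18 stood at -0.68. That list of 3 did not pass (adjusted p = 0.0843), and passed with no filter (adjusted p = 0.0435).

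The iron deficiency list did not pass at 3 h (adjusted p = 0.321), although its regulator PYE rose by 0.80. None of the measured members of the methionine cycle, ribosomal protein and cell cycle lists changed over all probe sets, and 1 methionine cycle member rose when adjusted over the list alone. Their adjusted camera p-values were 0.227, 0.454 and 0.900. WRKY53 and STZ of the touch list stood at 0.34 and 0.27. STZ differed widely between replicates, with signals of 147.9 and 748.1 at 0 h and 152.8 and 1059 at 3 h. Mean signals of STZ at 12, 24, 48 and 72 h were 91.9, 68.6, 89.6 and 90.0, against 448.0 at 0 h. Those of WRKY53 were 56.4, 44.5, 34.7 and 33.4, against 81.2 at 0 h. Calls of both at these later times are not given here. AT4G28100 and GSO1 of the endodermis list stood at 0.02 and -0.17, AGL42 of the root tip list at 0.15, and LHCB4.1 and RCA of the green tissue list at -0.51 and -0.38. In all, 1755 probe sets passed at 3 h, 796 higher and 959 lower, and 855 of them differed at least 2-fold. Fitted with the 3 h and 0 h arrays alone, 922 passed.

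**Figure D1:**
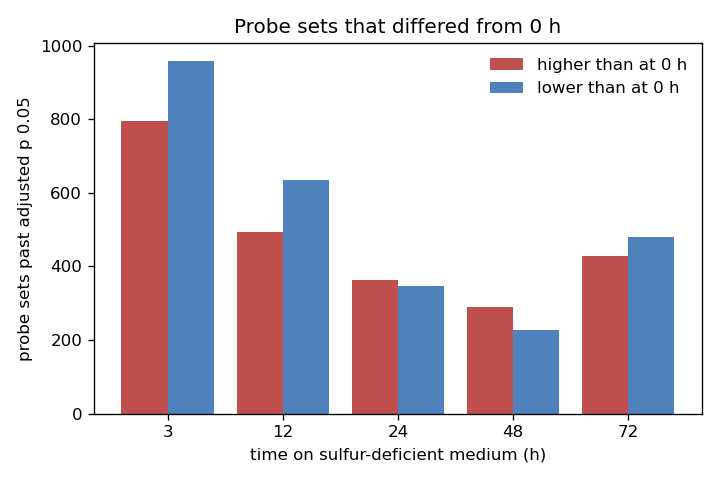
Number of probe sets past an adjusted p of 0.05 (y axis) that were higher (red) or lower (blue) than at 0 h, at each time on sulfur-deficient medium in hours (x axis). The bars were tallest at 3 h, with 796 higher and 959 lower, and lowest at 48 h, with 289 higher and 227 lower.

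At 12 h both sulfur deficiency markers were still higher than at 0 h, BGLU28 by 4.04 ± 0.31 and AT1G04770 by 1.82 ± 0.18 on the log2 scale (SE, adjusted p = 3.97e-06 and 4.16e-05). In sulfate assimilation APS4 fell by 0.87 ± 0.20 (-0.58 and not past the threshold without 12 h replicate 2) and APS3, at 0.50, passed only when adjusted over the list alone. None of the 4 glucosinolate genes passed, with BCAT4 at -0.42. Other rises were 4.32 for AT1G49000, 3.68 for AT1G12030 (0.97 and not past the threshold with an offset), 2.66 for AT1G75290, 2.59 for the cysteine proteinase CP1, 2.49 for AT4G09110, 2.22 for AT1G75280, 2.17 for AT5G51440, 2.06 for AT4G32950 and 2.04 for the sugar transporter family gene AT3G05400. GSTU25 rose by 1.36 and GI by 1.14. PYE rose by 0.73, a call lost without 0 h replicate 2 or any 1 array of 12, 24, 48 or 72 h. AT1G49000, AT1G12030, AT1G75290, AT4G09110, AT4G32950 and AT3G05400 were below the 40th percentile on both 0 h arrays. AT1G12030 was below it on both 12 h arrays as well. With an offset AT1G49000 stood at 2.06, AT1G75290 at 1.53 and AT3G05400 at 1.25, all past the threshold.

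The lowest values at 12 h were -4.92 for GAT1_2.1, -3.93 for AT3G01175, -3.45 for AT3G23880, -3.44 for AT1G26390, -3.36 for AT3G15450, -3.21 for AT1G34510, -3.20 for AT1G80380, -3.02 for AT5G56100 and -2.96 for both AT1G33055 and AT1G26380. The berberine bridge enzyme-like genes AT1G26380 and AT1G26390, and AT1G34510, were below the 40th percentile on both arrays of each group from 12 h on, and AT3G01175 and AT3G23880 on both 12 h arrays, so the size of their falls is uncertain. AT3G01175 stood at -2.27 with an offset and at -2.35 without 12 h replicate 1, and passed in both. The auxin response list shifted downward (adjusted p = 0.0389 with camera, adjusted p = 0.654 with an estimated correlation), with 1 of 3 members lower over all probe sets and 2 adjusted over the list alone. WES1 fell by 1.45. The list's call was lost without 0 h replicate 1 (adjusted p = 0.173), without 12 h replicate 2 (adjusted p = 0.298) and with no filter (adjusted p = 0.0598). Both green tissue genes fell, with differences of -0.90 for RCA and -0.80 for LHCB4.1, as did the nitrate-responsive regulator AT1G68670, at -0.70. The calls of RCA and LHCB4.1 were lost without any 1 of the 4 arrays compared, and AT1G68670 stood at -0.46 and did not pass without 0 h replicate 2. In all, 1129 probe sets passed, 493 higher and 636 lower. The count was 631 without 0 h replicate 2, 593 without 12 h replicate 1 and 570 without 12 h replicate 2.

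At 24 h BGLU28 was higher by 4.98 ± 0.31 and AT1G04770 by 1.85 ± 0.18 (SE, adjusted p = 9.11e-07 and 5.82e-05). APS4 fell by 1.04 ± 0.20, APS3 stood at 0.35, and BCAT4 at -0.51 passed only when adjusted over its list alone. AT1G12030 rose by 3.96, AT1G49000 by 3.85, AT1G75290 by 2.78, AT3G05400 by 2.61, AT1G75280 by 2.55, CP1 by 2.45, AT4G31330 by 2.19, AT2G43590 by 1.92 and AT3G28750 by 1.89. With an offset AT1G49000 stood at 1.69 and no longer passed (adjusted p = 0.0531), while AT1G12030 at 1.15, AT1G75290 at 1.62, AT3G05400 at 1.71 and AT3G28750 at 1.07 did. The lowest differences were -4.54 for AT1G26390, -3.91 for GAT1_2.1, -3.39 for both AT1G26380 and AT1G34510, -2.56 for AT4G27280, -2.44 for AT3G45730, -2.42 for AT2G41810, -2.32 for AT1G80380, -2.25 for AT5G66650 and -2.23 for AT1G19530. Without 0 h replicate 2 AT3G28750 stood at 1.22 and AT4G27280 at -1.64, and without 24 h replicate 1 AT5G66650 stood at -1.43, none past the threshold. AT3G28750 at 0 h, and AT3G45730 and AT1G19530 at 24 h, were also below the 40th percentile on both arrays. So was AT1G12030 at 0 h and at 24 h. The auxin response list shifted downward (adjusted p = 0.00360 with camera, adjusted p = 0.327 with an estimated correlation), with GH3.3 and WES1 both lower by over 1. GSTU25 rose by 1.29 and GI by 1.31. EXPA7 and EXPA18 also fell, at -1.15 and -1.27, after -0.68 and -0.67 at 12 h, which did not pass. The call of EXPA7 at 24 h was lost without 0 h replicate 2 or any 1 array of 12, 24 or 48 h. RCA and LHCB4.1 stood at -0.03 and 0.05. In all, 709 probe sets passed, 363 higher and 346 lower. The count was 352 without 0 h replicate 2, 158 without 24 h replicate 1, 340 without 24 h replicate 2 and 451 with no trend of the prior variance.

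At 48 h the rise of BGLU28 was 5.77 ± 0.31 and that of AT1G04770 2.14 ± 0.18 (SE, adjusted p = 1.33e-07 and 1.24e-05). APS4 fell by 2.52 ± 0.20 on the log2 scale (adjusted p = 6.54e-06), from a signal of 1783 ± 34.3 (SD, n = 2) at 0 h to 314.9 ± 61.0 (SD, n = 2). When adjusted over the list alone, APS3 and SIR also passed, at 0.47 and 0.34. BCAT4 fell by 0.71, a call lost without any 1 of the 4 arrays compared, and the other 3 glucosinolate genes did not pass. AT1G12030 rose by 5.00, AT3G05400 by 3.96, AT1G75290 by 3.18, AT1G75280 by 2.80, AT4G31330 by 2.55, CP1 by 2.40, AT2G43590 by 2.06 and AT2G40250 by 1.87. AT2G40250 was below the 40th percentile on both 0 h arrays, and stood at 2.82 without 0 h replicate 1 and at 0.91, not past the threshold, without 0 h replicate 2. The lowest differences were -5.32 for AT1G26380, -4.21 for AT1G26390, -3.72 for GAT1_2.1, -3.19 for AT2G41810, -3.13 for AT1G34510, -2.52 for AT2G25510, -2.36 for AT5G56100, -2.22 for AT5G48430 and -2.21 for AT3G45730. With an offset AT1G12030 stood at 1.81, AT1G75290 at 1.95 and AT1G26380 at -2.86, all past the threshold. AT2G41810, AT2G25510 and AT3G45730 were also below the 40th percentile on both 48 h arrays. The auxin response list shifted downward again (adjusted p = 0.00663 with camera, adjusted p = 0.386 with an estimated correlation), and not without 0 h replicate 1 (adjusted p = 0.0692). GSTU26 fell by 1.11, while GSTU25 rose by 1.25 and GI by 1.26. EXPA18 fell by 0.86, a call lost without any 1 array of 0, 12, 24, 48 or 72 h, and EXPA7 stood at -1.01 and did not pass. In all, 516 probe sets passed, 289 higher and 227 lower. The count was 283 without 0 h replicate 2, 255 without 48 h replicate 1 and 191 without 48 h replicate 2.

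At 72 h the glucosinolate genes were lower than at 0 h. BCAT4 fell by 3.49 ± 0.17 on the log2 scale (SE, adjusted p = 2.56e-08), from a signal of 727.1 ± 15.8 (SD, n = 2) to 64.8 ± 4.98 (SD, n = 2). AT2G31790 (UGT74C1) fell by 1.73 and GSTU20 fell by 1.07, while UGT74B1 stood at -0.48. The call of GSTU20 was lost without 0 h replicate 1, without 72 h replicate 2 and with no trend of the prior variance. Thus 3 of 4 members fell over all probe sets and 4 when adjusted over the list alone. The list shifted downward (adjusted p = 1.67e-06 with camera, adjusted p = 0.0486 with an estimated correlation). APS4 fell by 3.34 ± 0.20, to a signal of 176.2 ± 2.99 (SD, n = 2), with APS3 at 0.33 and SIR at 0.13. The coumarin synthesis gene AT3G12900 (S8H) of the iron deficiency list fell by 3.43 ± 0.90 (SE). That value rests on 72 h replicate 2, without which it was -1.37 and did not pass, and it was -5.49 without 72 h replicate 1 and -2.04 with an offset. That list had 1 of 4 members lower, 2 when adjusted over the list alone, and did not pass (adjusted p = 0.0537, and adjusted p = 0.306 with an estimated correlation). It passed with no filter (adjusted p = 0.0466), with the 72 h and 0 h arrays alone (adjusted p = 0.0476), and without 0 h replicate 2, 24 h replicate 1, 24 h replicate 2 or 72 h replicate 1 (adjusted p = 0.0104, 0.0286, 0.0316 and 0.00617).

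The highest values at 72 h were 7.19 ± 0.31 for BGLU28 (adjusted p = 1.12e-08), 6.38 for AT1G12030, 5.20 for AT3G05400, 3.64 for AT1G75290, 3.15 for AT1G75280, 2.89 for AT4G31330, 2.41 for AT3G28750, 2.39 for AT2G40250, 2.37 for AT1G04770 and 2.32 for CP1. The signal of AT3G05400 went from 13.8 ± 5.03 (SD, n = 2) at 0 h to 493.5 ± 4.72 (SD, n = 2), and that of AT1G75280 from 791.6 to 7011. Besides those already given, the lowest differences were -4.83 for AT1G26380, -4.24 for AT1G26390 and GAT1_2.1, -4.17 ± 0.25 for AT2G16005, -3.71 for AT5G38910, -3.01 for the methionine sulfoxide reductase MSRB6 and -2.58 for AT1G26250. Without 0 h replicate 1 AT5G38910 stood at -2.33 and AT1G26250 at -1.54, neither past the threshold, and without 0 h replicate 2 AT2G40250 stood at 1.44. With an offset AT1G12030 stood at 2.94, AT1G75290 at 2.34, AT3G28750 at 1.46, AT1G26380 at -2.67 and AT5G38910 at -2.46, all past the threshold. AT5G38910 was below the 40th percentile on both 72 h arrays. The auxin response list was lower (adjusted p = 0.0110 with camera, adjusted p = 0.273 with an estimated correlation). Its call was lost without 0 h replicate 1 (adjusted p = 0.0722). GSTU25 rose by 1.32, with GSTU26 at -0.75, and GI rose by 0.95, a call lost without 0 h replicate 2 and without 72 h replicate 1. EXPA18 fell by 0.80, a call lost without any 1 array of 0, 12, 24, 48 or 72 h, and EXPA7 stood at -0.73 and did not pass. In all, 906 probe sets passed, 427 higher and 479 lower. The count was 488 without 0 h replicate 2, 483 without 72 h replicate 1 and 322 without 72 h replicate 2.

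**Figure D2:**
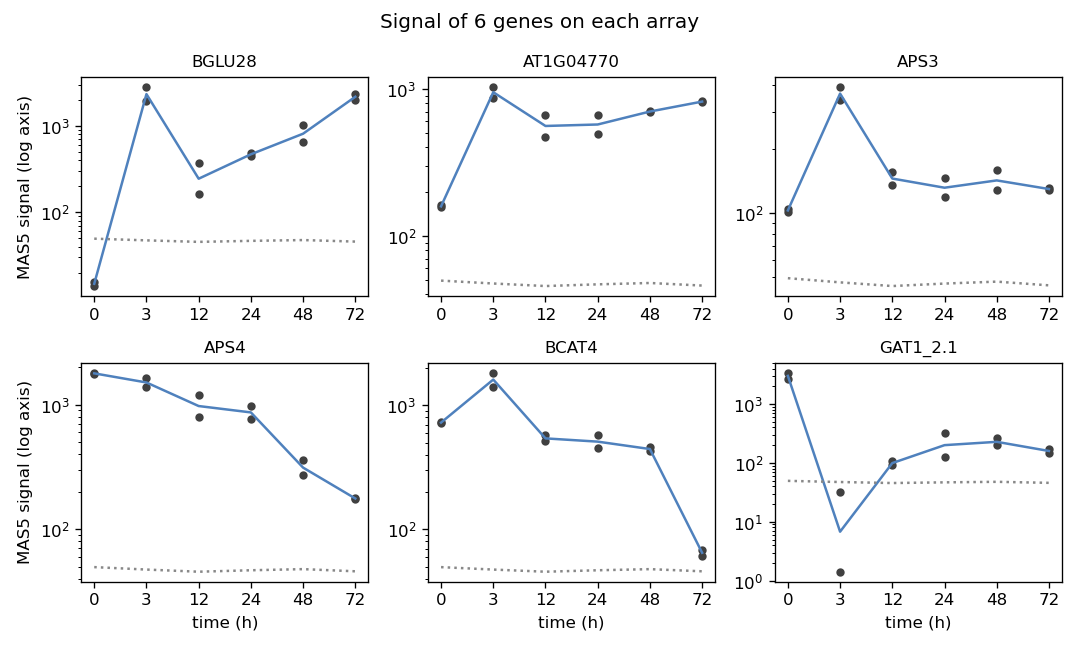
MAS5 signal (log axis) of 6 genes on each array at 0, 3, 12, 24, 48 and 72 h (x axis). Dots are the 2 arrays of a time, solid lines join their geometric means, and dotted lines show the mean 40th percentile of the arrays. BGLU28 had mean signals of 2377 at 3 h and 265.7 at 12 h, and BCAT4 had 1631 at 3 h and 64.8 at 72 h.

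The successive comparisons tested which of these differences changed between times. From 3 h to 12 h, BGLU28 fell by 3.25 ± 0.31 (adjusted p = 1.47e-04). The other lowest differences were -2.24 for AT4G37290, -2.23 for AT1G72060, -2.04 for AT2G23270 and -2.00 for AT5G39670. GAT1_2.1 rose by 3.87, CYP718 by 3.62, AT2G39040 by 2.22, AT1G19900 by 2.16 and AT5G61590 by 1.87. Without 3 h replicate 2 GAT1_2.1 stood at 1.61 and AT1G19900 at 1.39, and without 12 h replicate 2 AT1G72060 stood at -1.40, none past the threshold, while GAT1_2.1 stood at 6.13 without 3 h replicate 1. AT1G72060, AT2G23270 and AT5G39670 were below the 40th percentile on both 12 h arrays, and GAT1_2.1 and CYP718 on both 3 h arrays. With an offset GAT1_2.1 stood at 1.98, CYP718 at 2.14, AT1G72060 at -1.40 and AT2G23270 at -1.27, all past the threshold. APS3 fell by 1.33 and BCAT4 fell by 1.58. The glucosinolate list and the sulfate assimilation list both shifted downward (adjusted p = 1.06e-05 and 2.46e-04 with camera, adjusted p = 0.0335 for both with an estimated correlation). In all, 317 probe sets passed, 153 higher and 164 lower. The count was 549 without 3 h replicate 1, 114 without 3 h replicate 2, 64 without 12 h replicate 1, 144 without 12 h replicate 2, 133 with no trend of the prior variance and 183 with the arrays of both times alone.

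From 12 h to 24 h 4 probe sets passed with limma, and 1136 had an unadjusted p under 0.05. AT4G39675, the only named gene among them, rose by 1.27 ± 0.18. The count was 8 without either 0 h array, 2 without 12 h replicate 1, 0 without 12 h replicate 2 or any 1 array of 24, 48 or 72 h, 0 with no trend or no filter and 24 with the arrays of both times alone. From 24 h to 48 h 490 had an unadjusted p under 0.05. That is below the share of 0.05 of the 14678 tested that would be expected without any change. The adjusted threshold was passed by 3, all lower. They were AT2G16005, with a difference of -2.095, APS4, with -1.47, and AT3G07720, with -1.37. The count was 5 without either 0 h array, 9 without either 3 h array, 0 without either 24 h array, without 48 h replicate 2 or with no trend, and 21 with the arrays of both times alone. From 48 h to 72 h 717 had an unadjusted p under 0.05, also below that share. The adjusted threshold was passed by 12, 11 of them lower. The count was 7 without any 1 array of 12 or 24 h, 2 without 48 h replicate 1, 33 without 72 h replicate 1, 3 without 72 h replicate 2, 4 with no trend, 6 with no filter and 29 with the arrays of both times alone. BCAT4 fell by 2.78 ± 0.17 (adjusted p = 2.58e-06), and the differences were -2.18 for AT2G16005, -1.72 for AT2G31790 (UGT74C1), -1.70 for the carboxypeptidase scpl31 and -1.34 for AT4G01390. Without 72 h replicate 2 scpl31 stood at -1.08. Of the 9 gene values named for these 3 intervals, 8 lost the call in at least 1 of the leave-outs, all but BCAT4. The glucosinolate list shifted downward over this interval (adjusted p = 2.32e-14 with camera, adjusted p = 0.00599 with an estimated correlation).

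The other list shifts between successive times were lost with an estimated correlation. The ribosomal protein list went down from 12 h to 24 h, with a median of -0.15 (adjusted p = 0.0123, and adjusted p = 0.534 with an estimated correlation), and up from 48 h to 72 h, with a median of 0.09 (adjusted p = 0.0251, and adjusted p = 0.409 with an estimated correlation). With quantile normalization neither passed (adjusted p = 0.274 and 0.488). The first was lost without 12 h replicate 1 (adjusted p = 0.174). The second turned, to a median of -0.000356, without 48 h replicate 1 (adjusted p = 0.667), and was lost without 72 h replicate 1 (adjusted p = 0.0983) and with no filter (adjusted p = 0.0639). The iron deficiency list went down from 24 h to 48 h (adjusted p = 1.36e-04, and adjusted p = 0.117 with an estimated correlation). Sulfate assimilation went down from 48 h to 72 h (adjusted p = 0.0106, and adjusted p = 0.0847 with an estimated correlation), a call lost without 48 h replicate 2 (adjusted p = 0.0810). No member of these lists passed over all probe sets in those intervals.

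**Figure D3:**
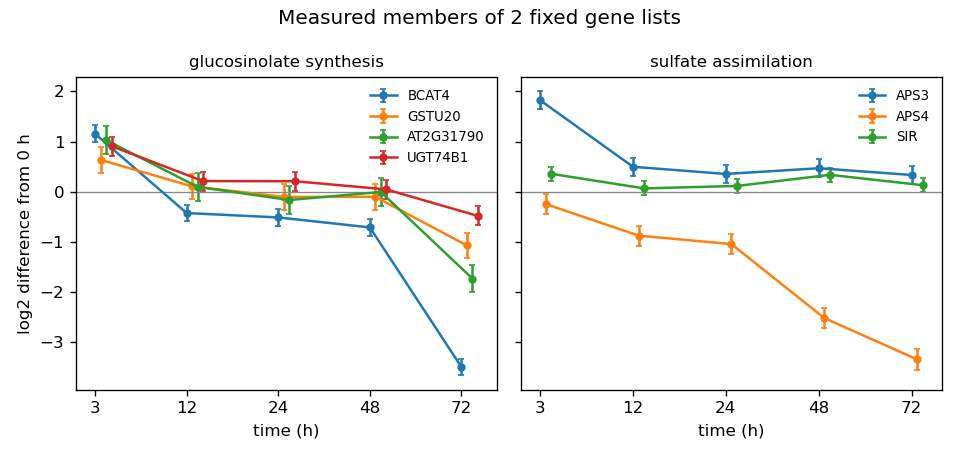
Log2 difference from 0 h (y axis) of the measured genes of 2 fixed lists at 3, 12, 24, 48 and 72 h (x axis). Dots are fitted differences and bars their standard errors. BCAT4 stood at 1.15 at 3 h and -3.49 at 72 h, APS3 at 1.82 at 3 h, and APS4 at -3.34 at 72 h.

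Over the whole course 1715 probe sets passed the F test. The 10 named genes with the smallest p were BCAT4, BGLU28, AT2G16005, APS4, AT3G05400, AT4G37290, AT1G75280, AT1G60750, AT1G80380 and AT4G39675. The largest difference from 0 h fell at 3 h for 908 of the 1715, at 12 h for 265, at 24 h for 113, at 48 h for 103 and at 72 h for 326. At all 5 times 135 probe sets were higher and 108 lower than at 0 h. They rest on the same pair of 0 h arrays. Between 3 h and 12 h, 762 calls were shared in the same direction, against 68.3 for independent lists of that length and 0 in simulated groups without change, and between 3 h and 72 h 443 were shared, against 54.5 and 0.05. The simulated groups hold no effects and so almost no calls, and the value for independent lists leaves out the shared 0 h arrays, so neither measures how many calls the shared arrays account for. The differences at 3 h and 72 h correlated across probe sets, which are not independent replicates, at 0.555, against 0.502 in the simulation, and their covariance was 0.165, against 0.0306. With 3 h and 72 h each set against a different 0 h array, a comparison added after these values were seen, the correlation was 0.320 and 0.382 and the covariance 0.113 and 0.126 for the 2 ways to assign the arrays. Many of the probe sets that moved most had no gene name here. The highest of them against 0 h differed by 6.61 at 72 h and the lowest by -6.65 at 24 h, or -3.47 with an offset.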

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

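The tests of RNA quality at 3 h, of 3 h and 12 h groups with 1 array each, and of the 25S and 5S rRNA controls, as well as the difference from 3 h to 72 h, were chosen only after the results were seen.

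Differences from 0 h that themselves differed between times were counted by direct tests: 317 probe sets from 3 h to 12 h, 4 from 12 h to 24 h, 3 from 24 h to 48 h, 12 from 48 h to 72 h, and 1256 from 3 h to 72 h. Leaving out 1 array moved each of these by over 1.5 times. The count from 3 h to 72 h was 665 without 3 h replicate 2, 785 without 72 h replicate 1 and 538 without 72 h replicate 2. That from 3 h to 12 h was 549 and 114 without 3 h replicates 1 and 2, and 64 and 144 without 12 h replicates 1 and 2. The others ranged from 0 to 8, from 0 to 9 and from 2 to 33, the highest of these without 72 h replicate 1. Among named genes, AT4G39675 rose by 1.27 from 12 h to 24 h. From 24 h to 48 h the differences were -2.095 for AT2G16005, -1.47 for APS4 and -1.37 for AT3G07720. From 48 h to 72 h they were -2.78 for BCAT4, -2.18 for AT2G16005, -1.72 for AT2G31790, -1.70 for scpl31 and -1.34 for AT4G01390. Of the 1256, 32 passed in opposite directions against 0 h at 3 h and 72 h, 24 of them higher at 3 h and lower at 72 h. BCAT4 and AT2G31790, named above and both of glucosinolate synthesis, had the largest such differences among named genes.

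More probe sets differed from 0 h at 3 h than at 12 h, 1755 against 1129. A test planned before its result was seen left out either 3 h array, and the smaller excess over 12 h was -137, without 3 h replicate 2, which met the criterion set for a count that rests on 1 array. That test set 1 array at 3 h against 2 at 12 h, so lost precision can lower the count at 3 h. Without 3 h replicate 1, at the same loss of precision, the count at 3 h stayed above that at 12 h. The outcome thus differed with the array left out, and the test leaves the question open. With 1 array left at both times, all 4 combinations gave more probe sets at 3 h, by at least 351, which argues against a single array as the whole source. RNA quality and time of day stay open. Of the actin and GAPDH ratios of the 3 h arrays, 2 of 4 lay outside the range of the 10 other arrays. The actin ratio of 3 h replicate 2 lay above it and the GAPDH ratio of 3 h replicate 1 below it. The ubiquitin ratio, left out of that test, was also highest in 3 h replicate 2, so 2 controls were highest on that array. GI, the only clock gene measured, passed at all 3 of the times 24, 48 and 72 h. It passed at 3 h and 12 h as well. The length of sulfur deficiency, as the design names it, may also account for the difference in counts and was not separable from RNA quality and time of day.

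The 25S rRNA control probe set, which is outside the comparisons, was brighter late in the course, with a mean signal of 1906.8 ± 1260 (SD, n = 2) at 48 h and 1133.4 ± 134 (SD, n = 2) at 72 h, against 218.6 ± 190 (SD, n = 2) at 0 h. The 48 h arrays read 1016 and 2798 and the 0 h arrays 84.1 and 353.1, so the size of the difference rests on single arrays. The pattern does not rest on 1 bright array, since without it the lowest late array was still 1.84 times the highest earlier one. RNA breakdown of the kind that raises the actin 3' to 5' ratio is argued against, since 0 of the 4 late arrays lay above the range of the earlier ones. The 5S rRNA control read 37.3 and 131.6 at 48 h, inside the range of the 8 earlier arrays, 33.4 to 345.9, and 251.6 and 363.9 at 72 h, so it did not brighten with 25S at 48 h. Carry-over of 25S rRNA alone into labelling and a change with time in the roots may each account for it and stay open.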

How the results depend on the processing

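The difference from 3 h to 72 h was added after the data were examined. Of the 191 gene values that passed, none changed sign in any of the 19 settings, of those in which it was tested. Their calls held less well: 117 passed in every setting in which they were tested, 71 were lost when 1 or another array was left out, and 47 in at least 1 other setting. The most were lost without 0 h replicate 2, 36 of the 184 tested, then with no trend and without 24 h replicate 1, 31 of 191 each. Counts stayed within 1.5 times the reported ones except as follows and when 1 array was left out; the cause was not tested. With the compared arrays alone the counts were 922 at 3 h, 183 from 3 h to 12 h, 24 from 12 h to 24 h, 21 from 24 h to 48 h and 29 from 48 h to 72 h, with 2 lists at 48 h. With no trend they were 451 at 24 h, 133 from 3 h to 12 h, 0 from 12 h to 24 h, 0 from 24 h to 48 h and 4 from 48 h to 72 h. With no filter they were 0 from 12 h to 24 h and 6 from 48 h to 72 h, with 3 lists at 3 h and 0 at 12 h. With an estimated correlation 0 lists passed at 3, 12, 24 and 48 h, 1 at 72 h and 3 between successive times.

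Leaving out 1 array at a time, where the lone array is assumed to vary like the other groups, gave 1175 to 1695 probe sets at 3 h, 570 to 1318 at 12 h, 158 to 906 at 24 h, 191 to 647 at 48 h, 322 to 1114 at 72 h, 64 to 549 from 3 h to 12 h, 0 to 8 from 12 h to 24 h, 0 to 9 from 24 h to 48 h, 2 to 33 from 48 h to 72 h, 538 to 1577 from 3 h to 72 h and 1277 to 1927 over the course. Lists ranged from 0 to 1 at 12 h, 0 to 3 at 48 h, 1 to 3 at 72 h and 6 to 9 between successive times, and stayed at 1 at 3 h and 24 h. The median of the ribosomal protein list from 48 h to 72 h ranged from -0.000356, without 48 h replicate 1, to 0.12, against 0.09 with all arrays.

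Over all probe sets tested, the replicate numbers showed no general pairing of the arrays. The differences between replicates 1 and 2 of a group correlated between groups at -0.231 to 0.198 over 15 pairs of groups, and 1 pair was over 0.1. STZ, AT1G26250, AT5G38910 and AT4G27280 differed between replicates in the same sense at 0 h and 3 h. The signals of AT5G38910 were 300.6 and 44.4 at 0 h and 254.2 and 45.0 at 3 h. AT5G48430 and GAT1_2.1 differed in opposite senses, GAT1_2.1 with both 3 h arrays below the 40th percentile. How many genes went each way was not counted. A link between same-numbered arrays of some groups, or for some genes, is not excluded. With the replicate block, 1648 probe sets passed at 3 h, 1069 at 12 h, 632 at 24 h, 493 at 48 h and 837 at 72 h. The iron deficiency list at 72 h, which did not pass in the reported fit, passed with the block (adjusted p = 0.0385). At 48 h that list passed with the compared arrays alone (adjusted p = 0.0279), without 0 h replicate 2 (adjusted p = 0.0271) and without 48 h replicate 2 (adjusted p = 0.0244). Without detection calls, differences of dim probe sets are limited by an unknown background. With an offset, BGLU28 at 3 h went from 7.29 to 6.24 and AT1G12030 at 72 h from 6.38 to 2.94.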

Other observations

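The gene families and the carbon starvation list were chosen after the data were examined, and the predictions for that list were set before its values were seen.

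Among 30 families of genes that share a symbol stem, UDP-glycosyltransferases (UGT), enzymes that join sugars to small molecules, shifted upward at 3 h (adjusted p = 0.0228 with camera, adjusted p = 0.371 with an estimated correlation). Of 33 measured members 11 rose and 3 fell. UGT74B1 of the glucosinolate list has this stem too, so the family result is not separate from that list. UGT84A1 rose by 2.14, UGT78D1 by 1.91 and UGT87A2 by 1.67, while UGT71C2 fell by 1.53. At the later times 5 to 9 members rose and the family did not pass (adjusted p = 0.114, 0.138, 0.0514 and 0.287 with camera). The xyloglucan endotransglucosylase/hydrolases (XTH), which remodel cell walls, shifted upward at 48 h (adjusted p = 0.0330 with camera, adjusted p = 0.748 with an estimated correlation), with 2 of 7 members higher, XTH18 by 1.69 and XTH19 by 0.83. It did not pass at 24 h or 72 h (adjusted p = 0.138 and 0.130), although 3 members were higher at each, with XTH18 at 1.47 and 2.03, and whether the shift differed between times was not tested.

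Genes known to rise in darkness or when sugar is short, together with the leucine breakdown pathway, were lower at 3 h. Of 24 listed genes 7 had a named probe set that was tested, and 6 of them fell. The differences were -2.51 for ATL8, -2.22 for AT2G32150, -2.04 for AT4G27450, and -1.68, -1.57 and -0.78 for the leucine breakdown genes IVD, MCCA and MCCB, while ETFQO stood at -0.11. A candidate explanation is that the 0 h roots were in a carbon-starved state that had ended by 3 h. The 0 h roots were moved to fresh medium as well, and how long they stayed there is not given, so time since transfer stays open as well. The list was tested alone, so its p-values here and below are not adjusted over lists. Its median at 3 h was -1.68 (p = 2.84e-07 with camera, p = 0.0414 with an estimated correlation). This met the criterion set beforehand, but the fall is the observation itself, and other explanations predict it as well, so it does not tell them apart. Noise of dim probe sets is argued against, since the median kept 96.4% of its size with an offset. The list was written after other genes with large falls at 3 h had been seen, which were left out of it, and no sugar was measured. The list was lower at the later times too, with medians of -1.66 at 12 h, -0.92 at 24 h, -0.74 at 48 h and -1.20 at 72 h. The unadjusted p-values were 2.61e-09, 1.57e-05, 1.02e-05 and 1.26e-07 with camera, and 0.0240, 0.0725, 0.0679 and 0.0374 with an estimated correlation. Of the 7 members, 6 fell at 12 h and at 72 h, and 2 at 24 h and at 48 h. All these comparisons rest on the same pair of 0 h arrays. The list went up from 12 h to 24 h, with a median of 0.70 (p = 1.94e-06 with camera, p = 0.0534 with an estimated correlation). It went down from 48 h to 72 h, with a median of -0.32 (p = 0.00137 with camera, p = 0.158 with an estimated correlation). Without 48 h replicate 1 that median was -0.13 and the call was lost. If 0 h, 24 h, 48 h and 72 h fell at the same hour of the day, which the labels do not say, the hour of harvest would not account for the lower values at those later times. That hour and an effect of sulfur deficiency itself stay open.

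The measured green tissue genes passed at 12 h, with LHCB4.1 at -0.80 and RCA at -0.90, and at none of the other times against 0 h. The changes of both from 12 h to 24 h, 0.85 and 0.87, did not pass.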
